A study of Homo sapiens with 16 samples.

How the data were processed

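Total RNA of MIA PaCa-2 cells, an established human pancreatic ductal adenocarcinoma line, was measured on 16 single-colour Cy3 arrays. The cells carried a doxycycline-inducible vector for a scramble hairpin or for a short hairpin RNA (shRNA) against RINT1. Per the labels' protocols, doxycycline at 1 µg/ml was added on the day after seeding and 200 ng of RNA was labelled with a low-input amplification kit. Cells were sampled at 0, 24, 48 and 96 h, which gave 8 groups of 2 replicates. The labels call these replicates biological. The sequences of the hairpins are not given in the sources used here.

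Each deposited scanner table holds the intensity of every spot of one array on a linear scale, per the file headers. Images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the processed signal is background-subtracted and spatially detrended, and spots near background carry a surrogate value in its place. The probe positions are those of hg19, per the file headers. The authors also deposited a value table on the log2 scale for the same arrays. Set against the scanner values of the same probes, its columns correlated with log2 processed signal minus the array's 75th percentile at r = 1 for every array. The median absolute difference was 0.0045, and column medians ran from -3.58 to -3.12. Its scale and centring were thereby settled, and no value in it is a ratio with a direction. The table served as an alternative.

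Control spots and spots marked as outliers were left out, spots of a probe were averaged, and log2 processed signal was reduced by each array's 75th percentile. Of 42405 probes, 224 were left out because all their spots were marked on at least 1 array. Gene names are those of the files. An accession in the reference table was found for 27241 probes, and 1309 genes had their symbol updated through it. The files named 30387 probes for 21338 genes. A probe entered the tests when it was well above background on both arrays of at least 1 group. A gene was represented by the probe with the highest mean signal over all 16 arrays, and other probes of a named gene are given where they differ. This left 20557 features, 14923 of them with a gene name.

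Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and version 1.17.8 of data.table, with 1 mean per group over all 16 arrays, so that every comparison shared one estimate of the spread. The residual degrees of freedom were 8 and the moderated total was 10.06. Adjusted p-values are Benjamini-Hochberg values over all features of a comparison, and a feature was called at an adjusted p under 0.05. SE is the standard error of the log2 change. The comparisons were the change from 0 h within each line, the difference between lines at each time, and the difference between the changes of the lines. This last quantity, the change in shRINT1 cells minus the change in scramble cells over the same time, is named the RINT1 hairpin response. A positive response can come from a rise in shRINT1 cells or from a fall in scramble cells. Its value at 96 h was also set against those at 24 h and 48 h. All scramble arrays were on one slide and all shRINT1 arrays on another, so line and slide cannot be told apart in a difference between lines at one time. Changes within a line, the hairpin responses and their differences compare arrays of the same slide first. Within each slide, the arrays of 0 and 24 h lay in row 1 and those of 48 and 96 h in row 2. The arrays of 0 and 48 h lay in columns 1 and 2, and those of 24 and 96 h in columns 3 and 4. The number of arrays limits the precision.

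Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with fry, which does not set a list against other genes. Counts of members adjusted over the list alone are given beside those over all features. The lists were the NRZ tether and ER SNAREs, ATF4 and CHOP targets, ER chaperones and ERAD, COPI, COPII and Golgi genes, autophagy and lysosome genes, cholesterol synthesis, fatty acid synthesis, p53 targets, DNA damage response and repair, G1/S and DNA replication, G2/M and mitosis, apoptosis regulators, NF-kB and secretory phenotype genes, interferon-stimulated genes, MAPK output and immediate early genes, EMT and extracellular matrix, SUMO pathway, oxidative phosphorylation, glycolysis and hypoxia, heat shock response, and markers of duct, acinar and islet, fibroblast and leukocyte cells.

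Groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. RINT1 is always named. For each hairpin response the rule names the 12 highest and 12 lowest called genes that have a symbol and were well above background on both arrays of all 4 groups, and for the other comparisons the 5 highest and 5 lowest. Up to 3 genes per time that were dim in shRINT1 cells at 0 h were to be given as bounds, and 0 met that rule. Where a gene named on other grounds was not well above background on any array of a compared group, its change is given as a bound ("at least"), with each such array at the higher of the gene's signal and the lowest signal of a probe well above background on it. For each list it names up to 4 called members with the smallest p, or the 2 with the smallest p where 0 were called. Symbols of predicted genes and non-coding transcripts were counted but not named. Some genes that the rule names are not reported here.

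The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, only the 12617 features above background on all 16 arrays, the mean of a gene's probes, eBayes with trend and robust, the replicate number as a block, the value table, the list tests above, and leaving out each array in turn. A fit with slide as a random block was planned and could not be estimated. A common floor on all arrays, a correction for the GC content of the probes, the comparison of the responses at 96 h and 48 h and 26 gene families were added after seeing the data.

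The fit was tested on simulated data with the 20557 features and the spread of the real arrays, for the hairpin response at 96 h. Of 67 genes changed by 0.5 on the log2 scale 0 were called, of 67 changed by 1 the share called was 20.9%, and of 66 changed by 2 it was 66.7%. The mean estimates were 0.42, 1.10 and 2.08, and 4 of 62 calls were wrong. Only these genes were changed, far fewer than the 2829 features called in the real response at 96 h. The Benjamini-Hochberg cutoff depends on how many features change, so these shares are not the sensitivity of the real comparison. A higher share at a change of 2 had first been set as the pass mark. The simulation missed it, and the mark was then replaced by limits on bias and on wrong calls. The 8 comparisons with no simulated change gave 0 calls, and a list of 27 genes shifted by -0.5 was called with 0 other lists. Each gene was drawn independently, so the simulated lists held no correlation between genes. The simulation therefore cannot vouch for the list calls in the real data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.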

Results

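Transcript levels were measured in MIA PaCa-2 pancreatic cancer cells in which doxycycline switched on a hairpin against RINT1 (shRINT1) or a scramble hairpin. RINT1 belongs to the NRZ complex, which tethers vesicles returning from the Golgi to the endoplasmic reticulum (ER). Both lines were sampled at 0, 24, 48 and 96 h of doxycycline with 2 arrays per group, 16 in all. Each array held 62976 spots, 58717 of them not controls, with 0 saturated. The spike-in detection limit on a log10 scale was -1 on replicate 2 of scramble at 0 h and 0.517 to 1.69 on the other arrays. The 75th percentile of the signal ran from 478 to 755. Arrays of 0 and 24 h had negative-control signals of 21.3 to 22.8 and 61.7% to 65.5% of spots well above background. Arrays of 48 and 96 h had 31.1 to 49.8 and 44.3% to 55.4%, in both lines. Agreement of replicates was computed on the 12617 features above background on all 16 arrays, without the dimmer ones. Replicates of a group correlated at 0.984 to 0.997 across these features, which are not independent replicates. The SD of their log2 difference was 0.18 to 0.40. The first principal component of the same features, with 30.4% of the variance, placed the shRINT1 arrays of 96 h at 43.3 and 45.4. All others lay between -19.8 and 10.1.

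RINT1 itself was lower in shRINT1 cells at every time after doxycycline. Its level was 25.1% of that in scramble cells at 48 h (log2 -1.99, adjusted p = 0.00111) and 31.6% at 96 h (log2 -1.66, adjusted p = 0.000229), after -1.36 at 24 h (adjusted p = 0.0167). Before doxycycline the difference was -0.33 with an SE of 0.20 (adjusted p = 0.631). All 6 shRINT1 arrays after doxycycline lay between 0.73 and 1.55 on the normalized log2 scale, and all scramble arrays lay between 2.57 and 3.14. Within the shRINT1 line the level fell from 0 h by 1.76 at 48 h (adjusted p = 0.0172) and by 1.27 at 96 h (adjusted p = 0.00151). At 24 h the change was -1.08 (adjusted p = 0.116), which left 47.3% of the 0 h level. In scramble cells RINT1 changed by -0.05, -0.10 and 0.07 at the 3 times, with adjusted p-values of 0.97, 1 and 0.942. The RINT1 hairpin response, the change in shRINT1 cells minus that in scramble cells, was -1.03 at 24 h (SE 0.28, adjusted p = 1), -1.67 at 48 h (adjusted p = 0.151) and -1.33 at 96 h (adjusted p = 0.0125). These values come from 1 probe with 10 spots per array, at chromosome 7, positions 105207999 to 105208058 of hg19. The response at 48 h passed the threshold with only features above background on all arrays (adjusted p = 0.0457), with trend and robust (0.0374) and without replicate 2 of shRINT1 at 0 h (0.0443).

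**Figure D1:**
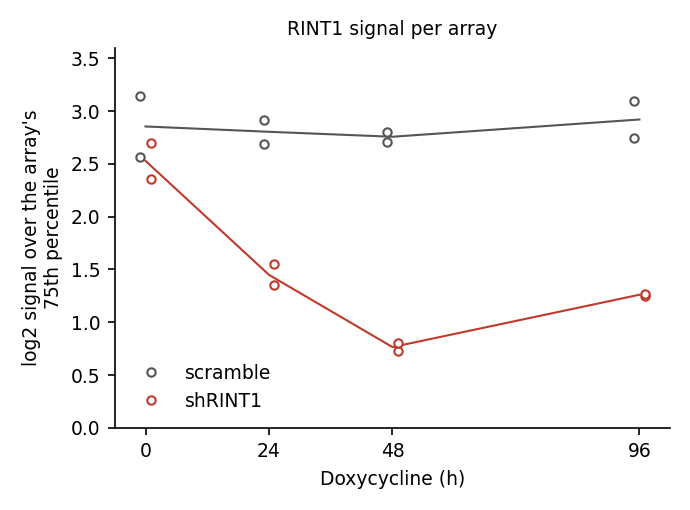
RINT1 signal on the normalized log2 scale (y axis) against hours of doxycycline (x axis) in scramble and shRINT1 cells; open circles are single arrays and lines join the means of 2 arrays. All 6 shRINT1 arrays after doxycycline lie between 0.73 and 1.55, and all scramble arrays lie between 2.57 and 3.14.

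By 96 h the hairpin response covered 2829 of 20557 features (13.8%), 1344 higher and 1485 lower, of which 1558 differed at least 2-fold (628 higher, 930 lower). The balance depended on the setting, with 1549 higher and 1275 lower among features above background on all arrays, 1674 and 1659 with a common floor and 1113 and 1613 under quantile normalization. Of the 12 lowest genes by the naming rule 5 belonged to the interferon-stimulated genes. OASL (log2 -3.12, SE 0.19, adjusted p = 2.79e-05, 8.66-fold lower), IFIT3 (-2.93, SE 0.19, adjusted p = 4.14e-05), IFIT2 (-2.89, SE 0.15, adjusted p = 1.45e-05), ISG15 (-2.83, SE 0.13, adjusted p = 1.45e-05) and IFIT1 (-2.71, SE 0.19, adjusted p = 5.38e-05) were lower in shRINT1 cells relative to scramble. IFIT proteins bind viral RNA, and ISG15 is a ubiquitin-like modifier. ISG15, at chromosome 1, positions 949567 to 949626 of hg19, rose by 1.80 in scramble cells and fell by 1.03 in shRINT1 cells over the same 96 h. PLAAT4, a phospholipase induced by retinoids and interferon, was at -2.78 (SE 0.22, adjusted p = 9.4e-05). The other low genes were LHPP, a phosphatase (-3.24, SE 0.18, adjusted p = 1.45e-05), MRC2, a collagen uptake receptor (-2.93, adjusted p = 0.000205), SHC2, an adaptor protein (-2.92, SE 0.68, adjusted p = 0.0185), SLC27A1, a fatty acid transporter (-2.88, adjusted p = 0.00014), FBXO2, which binds N-glycans (-2.84, adjusted p = 0.00767), and CORO2A, an actin-binding coronin (-2.76, adjusted p = 2.89e-05).

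Among the 12 highest genes at 96 h were CSF3, the granulocyte growth factor (2.65, SE 0.21, adjusted p = 7.8e-05, 6.26-fold), the vasodilator peptide gene ADM (2.02, SE 0.19, adjusted p = 0.000181), LMNB1 of the nuclear lamina (2.07, SE 0.32, adjusted p = 0.0025) and GRWD1, a factor in ribosome biogenesis (2.08, SE 0.19, adjusted p = 0.000154). SSH2, a cofilin phosphatase (2.89, adjusted p = 7.25e-05), and the salivary proline-rich genes PRH2 (2.41, adjusted p = 9.76e-05) and PRR4 (2.18, adjusted p = 0.0018) were also in this group. The highest estimate among the named genes was that of TAF15, an RNA-binding protein (3.45, SE 0.86, adjusted p = 0.0252). HSD17B10, a mitochondrial dehydrogenase (2.78, SE 0.15, adjusted p = 1.45e-05), NF2, which encodes merlin (2.16, adjusted p = 5.46e-05), and DYNLRB1, a dynein light chain (2.12, adjusted p = 0.000265), were in this group while falling in the scramble line. They changed by 0.43, 0.37 and 0.31 in shRINT1 cells and by -2.36, -1.79 and -1.82 in scramble cells.

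Other probes of some of these genes gave different values at 96 h. SSH2 had a further probe at 0.45, NF2 at 0.14, LHPP at -1.18, CORO2A at -1.55 and IFIT2 at -2.82. Those of PRH2, SHC2, SLC27A1 and CSF3 were not well above background on either array of at least 1 group. Of the 2829 called features, 796 had another tested probe. At least 1 such probe was called in the same direction for 248 and in the opposite direction for 18, adjusted over all tested probes. For 600 all other probes had the same sign as the called one. With no filter on dim probes 1465 features were called, and 1881 without replicate 1 of shRINT1 at 0 h. TAF15 lost its call with no filter (adjusted p = 0.059) and without either scramble array of 0 h (0.0523, 0.077), replicate 1 of scramble at 96 h (0.0813), replicate 2 of shRINT1 at 0 h (0.0744) or replicate 2 of shRINT1 at 96 h (0.0585). SHC2 lost its call with the mean of its probes (0.14) and without replicate 1 of scramble at 0 h (0.0507), replicate 2 of scramble at 96 h (0.0524) or either shRINT1 array of 0 h (0.0568, 0.0508). FBXO2 kept its call throughout, at -3.68 and -1.99 without replicates 1 and 2 of scramble at 0 h. Without single arrays TAF15 ranged from 2.57 to 4.33 and SHC2 from -3.73 to -2.11.

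**Figure D2:**
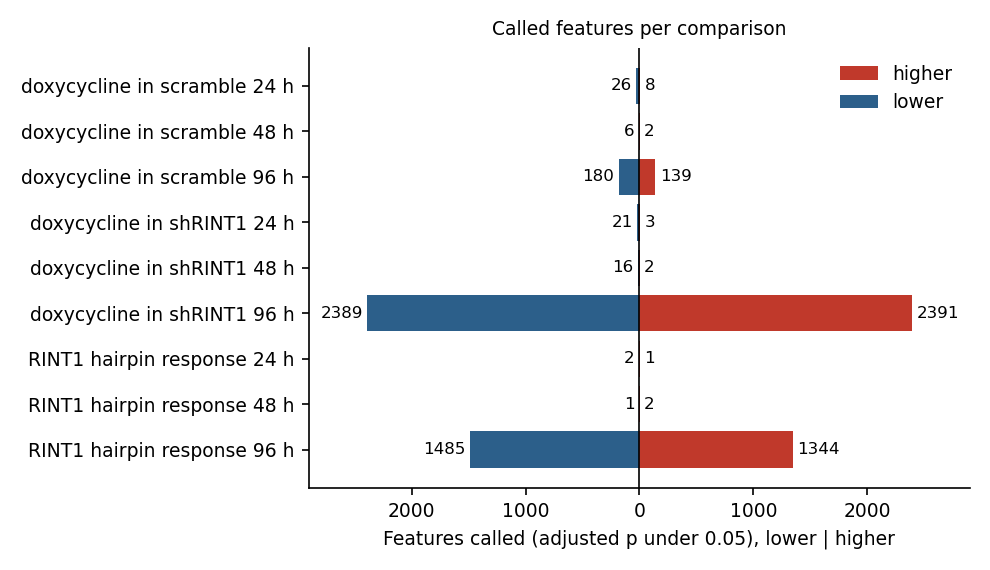
Number of features called by limma at an adjusted p under 0.05 (x axis, higher to the right and lower to the left of 0) for doxycycline in scramble cells, doxycycline in shRINT1 cells and the RINT1 hairpin response at 24, 48 and 96 h (y axis). The hairpin response had 3 calls at 24 h, 3 at 48 h and 2829 at 96 h.

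Of the 24 gene lists, 6 were called in the hairpin response at 96 h. Of 27 measured interferon-stimulated genes 21 were lower, 0 were higher and 6 did not pass, with a median of -1.83 (camera adjusted p = 1.1e-21, and adjusted p = 0.0019 with an estimated correlation). The count was 23 lower when adjusted over the list alone. BST2, which holds budding virus at the cell surface, was at -3.30 (SE 0.18, adjusted p = 1.45e-05) and HERC5, the ligase for ISG15, at -3.01 (SE 0.15, adjusted p = 1.45e-05), each well above background on 1 of 2 shRINT1 arrays of 96 h. Among the members that did not pass were OAS1 (adjusted p = 0.0676), RSAD2 (-1.71, adjusted p = 0.052), USP18 (-0.10), OAS3 and IFIT5 (0.27), named after their values were seen. OAS1 and OAS3 were not well above background on either shRINT1 array of 96 h, and RSAD2 was on 1 of 2. On single arrays the list's median stood 0.82 and 0.77 above the 0 h mean in scramble cells at 96 h, and at -1.02 and -1.04 in shRINT1 cells.

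Of 34 genes of G1/S and DNA replication 14 rose relative to scramble and 0 fell, with 24 higher when adjusted over the list alone and a median of 0.79 (camera adjusted p = 4.12e-11, and adjusted p = 0.0391 with an estimated correlation). CDT1, which licenses replication origins (1.69, SE 0.27, adjusted p = 0.00262), GINS3 of the replicative helicase (1.52, SE 0.15, adjusted p = 0.000265), CCNE2, a G1/S cyclin (1.45, adjusted p = 0.00402), and RRM2, which makes deoxynucleotides (1.17, adjusted p = 0.00307), were among them. Of 37 genes of G2/M and mitosis 13 were higher and 0 lower, with 20 higher when adjusted over the list alone and a median of 0.59 (camera adjusted p = 2.14e-10). This call was lost with an estimated correlation (adjusted p = 0.0902). The mitotic kinases PLK1 (1.27, SE 0.17, adjusted p = 0.00105) and AURKB (0.98, adjusted p = 0.00243), the spindle factor TPX2 (0.99, adjusted p = 0.00151) and CDCA8 (0.96, adjusted p = 0.00521) were examples.

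Of 27 genes of DNA damage response and repair 7 were higher and 1 lower, also when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.00619, and adjusted p = 0.159 with an estimated correlation). The histone variant gene H2AX was at 1.67 (SE 0.20, adjusted p = 0.000633), XRCC2 of homologous recombination at 1.43 (adjusted p = 0.00181), FANCA of crosslink repair at 0.91 (adjusted p = 0.00877) and the helicase gene BLM at 0.71 (adjusted p = 0.0132). The lower member was TP53BP1 (-0.63, adjusted p = 0.0448), named after its value was seen. Of 14 heat shock genes 3 were higher and 0 lower, with the same counts adjusted over the list alone and a median of 0.35 (camera adjusted p = 0.00979, and adjusted p = 0.434 with an estimated correlation). They were HSPA8 (1.17, adjusted p = 0.00528), DNAJB1 (1.05, adjusted p = 0.00151) and DNAJA1 (0.93, adjusted p = 0.00698), all chaperones or co-chaperones.

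Of 11 fatty acid synthesis genes 5 were lower and 0 higher, with the same counts adjusted over the list alone and a median of -0.65 (camera adjusted p = 0.000459). The call was lost with an estimated correlation (adjusted p = 0.0902), and the median was -0.43 without replicate 1 of scramble at 0 h. ACSS2, which makes acetyl-CoA from acetate (-1.45, SE 0.15, adjusted p = 0.000314), the fatty acid synthase gene FASN (-0.90, SE 0.19, adjusted p = 0.0115) and the desaturase genes FADS2 (-0.91, adjusted p = 0.0338) and FADS1 (-0.65, adjusted p = 0.0303) fell relative to scramble. The fifth was ME1 (-0.95, adjusted p = 0.042), named after its value was seen.

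**Figure D3:**
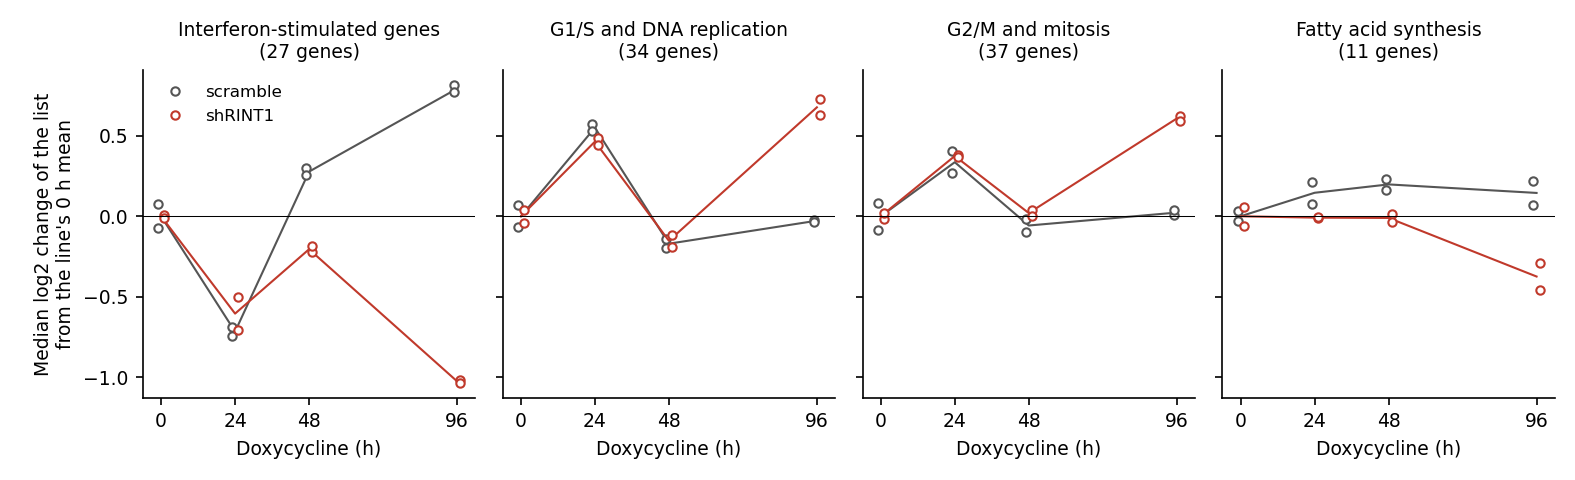
Median log2 change of a list's genes from the line's mean at 0 h (y axis) against hours of doxycycline (x axis) for interferon-stimulated genes (27), G1/S and DNA replication (34), G2/M and mitosis (37) and fatty acid synthesis (11); open circles are single arrays and lines join group means. Interferon-stimulated genes stand at 0.82 and 0.77 on the scramble arrays of 96 h and at -1.02 and -1.04 on the shRINT1 arrays.

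The other 18 lists were not called at 96 h, though single members passed the test over all features. Counts adjusted over the list alone were the same for these lists except where given. In the NRZ tether and ER SNAREs RINT1 was the only 1 of 8 genes called (list median -0.19, camera adjusted p = 0.829), with 2 higher and 1 lower when adjusted over the list alone. Its partners were ZW10 (0.57, adjusted p = 0.065) and NBAS (-0.62, adjusted p = 0.134), and the SNARE gene STX18 was at 0.92 (adjusted p = 0.0506). Of 24 ER chaperone and ERAD genes 3 were higher and 2 lower (median -0.07, camera adjusted p = 0.739). DERL1 (0.88, adjusted p = 0.00915), DERL2 (0.69, adjusted p = 0.0161) and DNAJC3 (0.85, adjusted p = 0.0323, the fifth, named after its value was seen) were higher, and HSPA5, the ER chaperone BiP (-1.21, adjusted p = 0.0253), and MANF (-0.63, adjusted p = 0.0189) were lower. Of 24 ATF4 and CHOP targets 3 were higher and 3 lower (median -0.11, camera adjusted p = 0.603). CHAC1, which degrades glutathione, was at 1.20 (adjusted p = 0.000781), the cystine transporter gene SLC7A11 at 1.14 (adjusted p = 0.014), NUPR1 at -1.04 (adjusted p = 0.00229) and VLDLR, not well above background on either shRINT1 array of 96 h, at least 2.42-fold lower (adjusted p = 0.0056). Of 28 COPI, COPII and Golgi genes 2 were higher, the SNARE gene GOSR2 (1.34, adjusted p = 0.000387) and CREB3 (0.81, adjusted p = 0.0109), and 1 was lower, SEC23A (-0.58, adjusted p = 0.0449), with 2 higher and 0 lower when adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.739).

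Of 24 autophagy and lysosome genes 2 were higher and 3 lower (median 0.01, camera adjusted p = 0.557). The autophagosome genes GABARAPL1 (-2.31, adjusted p = 0.000192), WIPI1 (-1.60, adjusted p = 0.000168) and UVRAG (-1.47, adjusted p = 0.00169) were lower, and ATP6V0D1 (0.93, adjusted p = 0.00467) and SQSTM1 (0.80, adjusted p = 0.0232, the fifth, named after its value was seen) were higher. Of 22 p53 targets 4 were higher and 4 lower (median 0.04 with a downward camera direction, adjusted p = 0.958). They included TIGAR (1.79, adjusted p = 0.000228), the p53 ligase gene MDM2 (at least 3.44-fold higher, adjusted p = 0.0015, not well above background on either scramble array of 96 h), GADD45A (1.45, adjusted p = 0.000385) and the pro-apoptotic BBC3 (-1.61, adjusted p = 0.000564). Of 22 apoptosis regulators 2 were higher and 3 lower (median -0.03, camera adjusted p = 0.739). PMAIP1 (-1.51, adjusted p = 0.00221), BIK (-0.91, adjusted p = 0.0119) and CFLAR (-0.95, adjusted p = 0.0202) were lower, and TNFRSF10A (0.78, adjusted p = 0.0128) and BCL2L1 (0.61, adjusted p = 0.049, the fifth, named after its value was seen) were higher.

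Of 15 NF-kB and secretory genes 3 were higher, the chemokine genes CXCL3 (at least 2.66-fold, adjusted p = 0.0359, not well above background on either scramble array of 96 h), CXCL2 (1.35, adjusted p = 0.00641) and CXCL1 (1.14, adjusted p = 0.00369), with a list median of 0.44 (camera adjusted p = 0.0602). Of 20 MAPK output genes 3 were higher, FOSL1 (1.88, adjusted p = 0.00107), DUSP5 (1.42, adjusted p = 0.0276) and JUN (0.67, adjusted p = 0.0288), with a list median of 0.18 (camera adjusted p = 0.273). Of 22 SUMO pathway genes 4 were higher, among them PIAS2 (1.13, adjusted p = 0.00884) and SENP5 (0.66, adjusted p = 0.0207), with a list median of 0.14 (camera adjusted p = 0.175). Of 23 cholesterol synthesis genes 4 were lower and 1 higher (median -0.25, camera adjusted p = 0.0666). MSMO1 (-1.27, adjusted p = 0.0147), INSIG1 (-1.19, adjusted p = 0.0292, the fifth, named after its value was seen), MVD (-0.97, adjusted p = 0.00252) and LSS (-0.81, adjusted p = 0.0212) were lower, and TMEM97 (0.70, adjusted p = 0.0174) was higher.

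Of 25 glycolysis and hypoxia genes 2 were higher and 5 lower, with 8 higher and 7 lower when adjusted over the list alone (median -0.03, camera adjusted p = 0.916). ALDOC (-2.66, adjusted p = 0.000153, well above background on 1 of 2 shRINT1 arrays of 96 h) and ENO2 (-1.12, adjusted p = 0.00158) were lower, and the glucose transporter gene SLC2A1 (0.93, adjusted p = 0.00332) and ADM were higher. Of 26 oxidative phosphorylation genes 1 was higher, UQCRFS1 (0.54, adjusted p = 0.0232), and 1 lower, NDUFV1 (-0.48, adjusted p = 0.0345), with 0 when adjusted over the list alone (median 0.08, camera adjusted p = 0.514). Of 14 EMT and matrix genes only TGFB1 was called (-0.99, adjusted p = 0.0262, well above background on 1 of 2 shRINT1 arrays of 96 h), and the list median was 0.08 with a downward camera direction (adjusted p = 0.921). Among markers of other cell types, COL1A2 was the only 1 of 3 fibroblast genes called (-1.53, adjusted p = 0.0027, list adjusted p = 0.296). Of 6 duct markers 0 were called (median -0.28, adjusted p = 0.557), with MUC1 at -1.32 and KRT19 at -0.95. Of 2 acinar and islet markers 0 were called (median -0.65, adjusted p = 0.514), with GCG at -0.54 and INS not well above background on any array of 96 h. Of 5 leukocyte markers 0 were called (median -0.09, adjusted p = 0.739), with CD14 at -0.90 and PTPRC at -0.44. GCG and PTPRC were well above background on 1 of 2 shRINT1 arrays of 96 h.

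At 24 and 48 h few genes were called in the hairpin response. RINT1 itself, at -1.03 and -1.67, was not among them, so few calls do not show that few genes changed. At 24 h limma called 3 features, with 573 at an unadjusted p under 0.05. HSD17B10 was higher (1.25, SE 0.15, adjusted p = 0.0487), and SNU13, a protein of the spliceosome and snoRNPs (-1.63, SE 0.19, adjusted p = 0.0487), and KIF5B, a kinesin motor (-1.59, SE 0.18, adjusted p = 0.0487), were lower. Further probes of SNU13 and KIF5B gave -1.62 and -1.54. At 48 h the 3 calls, with 1303 at an unadjusted p under 0.05, were HSD17B10 (2.06, SE 0.15, adjusted p = 0.0014), NF2 (1.63, SE 0.16, adjusted p = 0.0103) and SNU13 (-1.61, SE 0.19, adjusted p = 0.0455). A further NF2 probe, at chromosome 22, positions 30077460 to 30077519 of hg19, stood at -0.01, against 30094507 to 30094566 for the called probe. The other probes lay at chromosome X, 53458381 to 53458440 (HSD17B10), chromosome 22, 42071071 to 42071130 (SNU13), and chromosome 10, 32298000 to 32298059 (KIF5B). SNU13 and KIF5B changed by -1.49 and -1.43 in shRINT1 cells at 24 h, and HSD17B10 by -1.29 in scramble cells. Leaving out any 1 array moved the count at 24 h, to 167 (replicate 1 of scramble at 0 h), 111 (replicate 2 of shRINT1 at 24 h), 84 (replicate 2 of shRINT1 at 0 h), 9 and 5 (replicates 2 and 1 of scramble at 24 h) or 0 (each other array). That at 48 h moved to 208 and 10 without replicates 2 and 1 of shRINT1 at 48 h, 164 without replicate 1 of scramble at 0 h, 104 without replicate 2 of shRINT1 at 0 h and 1 without replicate 2 of scramble at 48 h. The 3 genes lost their calls at 24 h, and SNU13 at 48 h, with no filter and without most single arrays (adjusted p up to 0.38). NF2 at 48 h lost its call with no filter (0.0936), the mean of its probes (0.422), without replicate 2 of scramble at 48 h (0.0603) and without replicate 1 of shRINT1 at 0 h (0.0659).

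**Figure D4:**
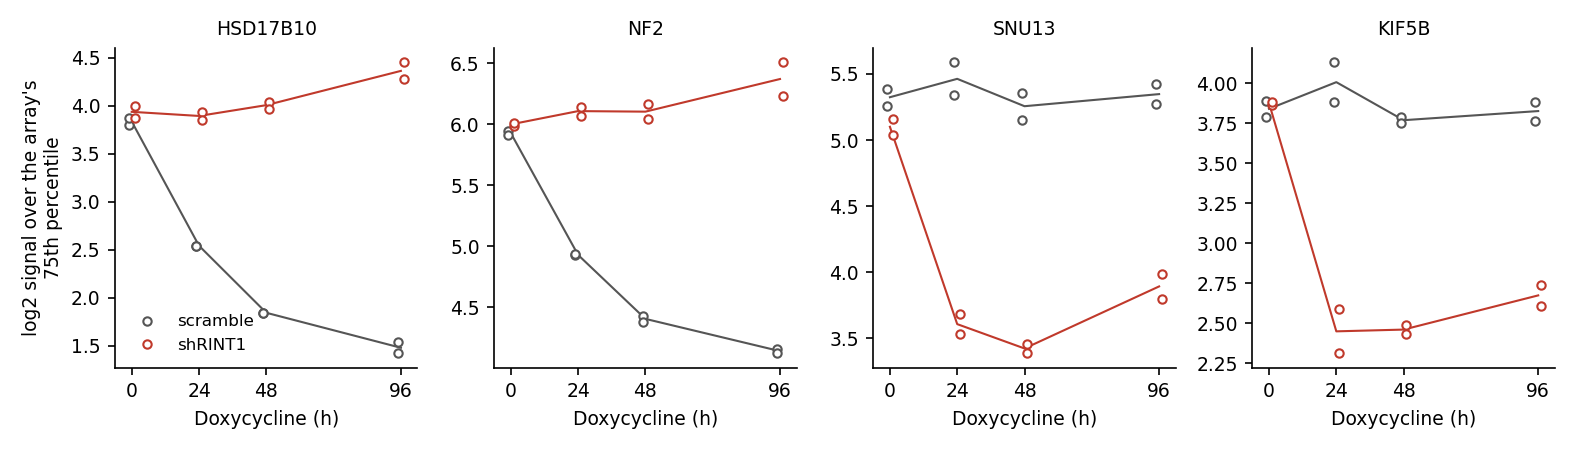
Normalized log2 signal of HSD17B10, NF2, SNU13 and KIF5B (y axes) against hours of doxycycline (x axes) in scramble and shRINT1 cells; open circles are single arrays and lines join the means of 2 arrays. HSD17B10 changed by -2.36 and NF2 by -1.79 in scramble cells by 96 h, and SNU13 changed by -1.49 and KIF5B by -1.43 in shRINT1 cells at 24 h.

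At 48 h 5 lists were called in the hairpin response, with 0 of their members called over all features. Interferon-stimulated genes had a median of -0.47 (camera adjusted p = 6.14e-11, and adjusted p = 0.0196 with an estimated correlation), with 10 lower when adjusted over the list alone. IFIT2 was at -0.92 (adjusted p = 0.115) and ISG15 at -0.74 (adjusted p = 0.168). The other 4 calls were lost with an estimated correlation. Fatty acid synthesis had a median of -0.21 (camera adjusted p = 0.00551, adjusted p = 0.206 with an estimated correlation), with ME1 at -0.76 and ACSS2 at -0.32. ER chaperones and ERAD had a median of -0.12 (camera adjusted p = 0.0122, adjusted p = 0.705 with an estimated correlation), with HSPA5 at -0.62 and MANF at -0.49. Cholesterol synthesis had a median of -0.17 (camera adjusted p = 0.0353, adjusted p = 0.5 with an estimated correlation), with MSMO1 at -0.71. EMT and extracellular matrix had a median of -0.22 (camera adjusted p = 0.0461, adjusted p = 0.206 with an estimated correlation), with CCN1 at -0.45 and SPARC not well above background on any array of 48 h. The EMT call was lost in 15 of 25 settings. Among them were the common floor (median -0.005), normexp (-0.08), quantile normalization (-0.20) and GC correction (-0.23). The EMT median was -0.11 without replicate 2 of shRINT1 at 48 h. The cholesterol call was lost in 6 of 25 settings. The ER chaperone call was lost in 5, with a median of -0.06 and -0.21 without replicates 1 and 2 of scramble at 0 h. The fatty acid call was lost in 4, with -0.33 without replicate 1 of shRINT1 at 48 h. At 24 h 0 lists were called. G1/S and DNA replication had a median of -0.14 (adjusted p = 0.0501), interferon-stimulated genes 0.10 (adjusted p = 0.387) and G2/M and mitosis 0.03 (adjusted p = 0.728).

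The response at 96 h differed from that at 24 h for 2887 features, 1402 higher and 1485 lower at 96 h (1660 and 1252 among features above background on all arrays), in a comparison that used no array of 0 h. CSF3 (3.07, SE 0.21, adjusted p = 4.48e-05), the AP-1 gene FOSL1 (2.72, SE 0.25, adjusted p = 0.000191), FAM111B (2.45, SE 0.54, adjusted p = 0.015), SSH2 (2.24, adjusted p = 0.000288) and TAF15 (3.38, SE 0.86, adjusted p = 0.0269) were the 5 highest by the naming rule. OASL (-3.21, adjusted p = 2.77e-05), PLAAT4 (-3.08, adjusted p = 6.92e-05), the RNA sensor gene IFIH1 (-2.97, SE 0.34, adjusted p = 0.000537), IFIT3 (-2.94, adjusted p = 4.34e-05) and LHPP (-2.94, adjusted p = 2.77e-05) were the 5 lowest. Further probes gave 0.28 for SSH2 and -1.15 for LHPP. The count was 1518 with no filter on dim probes and 1885 and 1882 without replicate 1 or 2 of scramble at 24 h. TAF15 lost its call with no filter and without any of 6 arrays (adjusted p 0.0515 to 0.0861), SSH2 with the mean of its probes (0.0511) and FAM111B without replicate 1 of scramble at 24 h (0.0518). FAM111B was at 1.82 and 3.09 without replicates 1 and 2 of shRINT1 at 24 h.

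Between 24 and 96 h, 8 lists differed. Of 27 interferon-stimulated genes 23 were lower (median -2.14, camera adjusted p = 1.49e-22, and adjusted p = 0.00165 with an estimated correlation). Of 34 G1/S genes 20 were higher, and 28 when adjusted over the list alone (median 0.92, camera adjusted p = 3.5e-14, and adjusted p = 0.0186 with an estimated correlation). The other 6 calls were lost with an estimated correlation. Of the G2/M genes 12 were higher, and 19 when adjusted over the list alone (median 0.59, camera adjusted p = 1.45e-09, adjusted p = 0.128 with an estimated correlation), and of the DNA damage genes 8 (median 0.40, camera adjusted p = 0.00298, adjusted p = 0.141 with an estimated correlation). Of the NF-kB genes 5 were higher, and 9 higher and 1 lower when adjusted over the list alone (median 0.65, camera adjusted p = 0.00305, adjusted p = 0.219 with an estimated correlation), and of the fatty acid synthesis genes 3 were lower, and 5 when adjusted over the list alone (median -0.55, camera adjusted p = 0.00305, adjusted p = 0.141 with an estimated correlation). Heat shock genes had 3 higher (median 0.32, camera adjusted p = 0.0296, adjusted p = 0.52 with an estimated correlation) and MAPK output genes 3 (median 0.17, camera adjusted p = 0.0296, adjusted p = 0.193 with an estimated correlation). The MAPK call was lost in 8 of 25 settings. Among them were only features above background on all arrays (0.429), the common floor (0.0607), quantile normalization (0.0696) and normexp (0.0529). The list had medians of 0.15 to 0.31 without single arrays. The heat shock call was lost in 5 of 25 settings. It had medians of 0.16 to 0.45 without single arrays. The fatty acid median was -0.37 without replicate 1 of scramble at 24 h. Set against 48 h, whose arrays lay in the same slide rows as those of 96 h, the response at 96 h differed for 1973 features, 717 higher and 1256 lower. The count was 909 with no filter, 1143 and 1076 without replicates 1 and 2 of scramble at 48 h and 1272 without replicate 1 of shRINT1 at 48 h. Interferon-stimulated genes were lower there too, 19 of 27 (median -1.61, camera adjusted p = 4.07e-19, and adjusted p = 0.00297 with an estimated correlation). G1/S genes were higher, 10 of 34 (median 0.74, camera adjusted p = 2.88e-13, and adjusted p = 0.0229 with an estimated correlation). This comparison was chosen after the data were seen.

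Changes in scramble cells cover doxycycline, days in culture and the scramble hairpin. At 24 h 34 features were called in these cells, 8 higher and 26 lower, with 2227 at an unadjusted p under 0.05. The replication-dependent histone genes H2BC7 (0.98, SE 0.12, adjusted p = 0.012) and H3C15 (0.90, adjusted p = 0.0438), the cell-cycle transcription factor gene E2F1 (0.96, SE 0.12, adjusted p = 0.0148), the kinetochore gene ZWINT (0.90, adjusted p = 0.0152) and ZNF367 (0.85, adjusted p = 0.0445) rose. The chemokine gene CCL5 (-2.06, SE 0.17, adjusted p = 0.00204), IFIH1 (-1.95, SE 0.24, adjusted p = 0.0123), RTP4 (-1.85, adjusted p = 0.00204), OASL (-1.53, adjusted p = 0.00237) and QPRT, an enzyme of NAD synthesis (-1.42, adjusted p = 0.0113), fell. The shRINT1 line had 24 calls at 24 h, 3 higher and 21 lower. The count in scramble cells was 14 with no filter (all lower), 243 with a common floor (146 higher, 97 lower), 123 among features above background on all arrays (68 higher, 55 lower), and 266, 14 and 83 without replicate 1 of scramble at 0 h, replicate 2 at 0 h and replicate 1 at 24 h. With no filter the 5 higher genes lost their calls, and RTP4 lost its call under quantile normalization (adjusted p = 0.338) and at -0.29 with the common floor (0.235). H3C15 lost its call in 13 of 26 settings (adjusted p 0.0501 to 0.204) and ZNF367 in 18 of 25 (0.0556 to 0.195). Without replicate 2 of scramble at 0 h E2F1 (0.0942), H2BC7 (0.0826), ZWINT (0.11), IFIH1 (0.104) and QPRT (0.0604) lost theirs. E2F1 (0.0556) and ZWINT (0.0622) also lost it without replicate 1 of scramble at 24 h, H2BC7 (0.0603) and IFIH1 (0.0537) without replicate 2, and QPRT under quantile normalization (0.0696) and after GC correction (0.0621).

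In scramble cells at 24 h 5 lists were called, 4 of them also with an estimated correlation. G1/S and DNA replication had a median of 0.58 (camera adjusted p = 2.82e-27, and 0.00201 with an estimated correlation), with 1 gene higher over all features and 24 higher when adjusted over the list alone. Interferon-stimulated genes had a median of -0.67 (camera adjusted p = 2.93e-22), with 8 lower and 15 lower when adjusted over the list alone, among them BST2 (-1.34, adjusted p = 0.00423) and HERC5 (-1.06, adjusted p = 0.00566). G2/M and mitosis had a median of 0.34 (camera adjusted p = 3.67e-17), with 0 called over all features and 17 higher when adjusted over the list alone. FOXM1, a driver of mitotic genes, was at 0.73 (adjusted p = 0.083) and CDCA8 at 0.61 (adjusted p = 0.11). DNA damage genes had a median of 0.19 (camera adjusted p = 5.57e-08), with FANCA at 0.85 (adjusted p = 0.0393) the only call over all features and 7 higher when adjusted over the list alone. Heat shock genes had a median of 0.14 (camera adjusted p = 0.0354, adjusted p = 0.683 with an estimated correlation), with HSPA1B at 0.51 and DNAJA1 at 0.38, neither called. This list call was lost in 9 of 25 settings, with a median of 0.24 without replicate 2 of scramble at 0 h.

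At 48 h 8 features were called in scramble cells, 2 higher and 6 lower, with 1509 at an unadjusted p under 0.05. HSD17B10 fell by 1.99 (SE 0.11, adjusted p = 6.7e-05), NF2 by 1.52 (SE 0.11, adjusted p = 0.000729), DYNLRB1 by 1.43 (SE 0.15, adjusted p = 0.0134) and the glycine transporter gene SLC6A9 by 1.09 (SE 0.13, adjusted p = 0.0276). The 2 higher genes were COL4A6 (bound 7.81-fold, adjusted p = 0.0134) and OR8U1 (bound 4.97-fold, adjusted p = 0.0461, well above background on 1 of 2 arrays of 48 h). Neither was well above background on either array of 0 h, and both were named after their values were seen. The lowest signal well above background was -5.92 and -6.45 on the scramble arrays of 0 h and -4.27 and -4.09 on those of 48 h. These 2 bounds include that difference in background and are not minimum rises of the transcripts. NF2 lost its call with the mean of its probes (adjusted p = 0.129), DYNLRB1 without replicate 2 of scramble at 0 h (0.076) or 48 h (0.0951), and SLC6A9 in 12 of 26 settings (0.0523 to 0.167), among them the mean of its probes. Of 6 lists called, interferon-stimulated genes had a median of 0.18 (camera adjusted p = 1.34e-10, and adjusted p = 0.0216 with an estimated correlation), with 6 higher when adjusted over the list alone, and IFIT3 at 0.84 (adjusted p = 0.106). The other 5 calls were lost with an estimated correlation. They were apoptosis regulators (median 0.16, adjusted p = 0.128 with an estimated correlation), G1/S and DNA replication (-0.15, 0.201), fatty acid synthesis (0.13, 0.201), EMT and matrix (0.12, 0.128) and cholesterol synthesis (0.09, 0.381). Single arrays moved these medians. Without replicate 1 of scramble at 0 h that of cholesterol synthesis was 0.02 and that of apoptosis regulators 0.09, and without replicate 2 those of G1/S and fatty acid synthesis were -0.05 and 0.30. The EMT median was 0.06 without replicate 2 of scramble at 48 h, and that of the interferon-stimulated genes 0.30. The count of features was 24 under quantile normalization, 5773 with no filter (5554 higher, 219 lower) and 45 with a common floor, and 221 without replicate 1 of scramble at 0 h, 21 without replicate 1 at 48 h and 4 or 5 without replicate 2 of scramble at 0 or 48 h, either scramble array of 96 h or any shRINT1 array of 0, 24 or 48 h.

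At 96 h 319 features were called in scramble cells, 139 higher and 180 lower. RTP4 (2.13, SE 0.16, adjusted p = 0.000304), IFIT3 (2.02, adjusted p = 0.000173), CCL5 (1.95, adjusted p = 0.000769), the pro-apoptotic PMAIP1 (1.88, SE 0.16, adjusted p = 0.000651) and ISG15 (1.80, SE 0.09, adjusted p = 2.99e-05) were the 5 highest by the naming rule. HSD17B10 (-2.36, adjusted p = 1.28e-05), DYNLRB1 (-1.82, adjusted p = 0.000567), NF2 (-1.79, adjusted p = 0.000103), SLC6A9 (-1.68, adjusted p = 0.000348) and SCLY, a selenocysteine lyase gene (-1.35, SE 0.22, adjusted p = 0.0181), were the 5 lowest. Further probes gave -0.20 for NF2 and -0.07 for SCLY, and that of SLC6A9 was not well above background on either array of at least 1 group. Of 27 interferon-stimulated genes 12 rose and 0 fell, with 19 higher when adjusted over the list alone and a median of 0.79 (camera adjusted p = 7.35e-24, and adjusted p = 0.00134 with an estimated correlation). HERC5 (1.47, adjusted p = 0.000304) and IFIT2 (1.33, adjusted p = 0.000408) were among them. The 3 other lists called lost their calls with an estimated correlation. They were apoptosis regulators (median 0.34, adjusted p = 0.21 with an estimated correlation), with 2 higher, PMAIP1 and HRK (0.70, adjusted p = 0.0127), and 6 higher when adjusted over the list alone, ER chaperones and ERAD (0.12, 0.518), with MANF at 0.65 (adjusted p = 0.0177), and MAPK output genes (0.22, 0.233), with MYC at 0.49 (adjusted p = 0.0464). The MAPK median was 0.14 without replicate 2 of scramble at 96 h, and this call was lost in 4 of 25 settings and the ER chaperone call in 5. Under normexp 1830 features were called (1390 higher, 440 lower), under quantile normalization 432 (140 higher, 292 lower) and with no filter 8751 (8157 higher, 594 lower). The count was 76 without replicate 2 of scramble at 0 h, 77 without replicate 2 at 96 h and 202 without either array of 24 h, and RTP4 lost its call under quantile normalization (adjusted p = 0.0774). SCLY lost its call with the mean of its probes (0.0761) and without replicate 2 of scramble at 0 h (0.103) or either scramble array of 96 h (0.0504, 0.0945).

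In shRINT1 cells set against their own 0 h arrays, 4780 features were called at 96 h, 2391 higher and 2389 lower, after 18 at 48 h (2 higher, 16 lower). Of 37 G2/M genes 26 rose (median 0.59, camera adjusted p = 2.45e-12, adjusted p = 0.0601 with an estimated correlation), and of 34 G1/S genes 24 rose (median 0.66, camera adjusted p = 8.21e-12, and adjusted p = 0.0341 with an estimated correlation). Of 27 interferon-stimulated genes 20 fell and 1 rose (median -1.01, camera adjusted p = 2.84e-12, and adjusted p = 0.0146 with an estimated correlation).

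Before doxycycline the lines already differed in 74 features, 46 higher and 28 lower in shRINT1 cells, with 2148 at an unadjusted p under 0.05. The hyaluronan synthase gene HAS3 (3.35, SE 0.21, adjusted p = 0.000108), F2RL2, a thrombin receptor gene (2.22, adjusted p = 0.00979), CYB5R2 (2.16, adjusted p = 0.0229), the laminin gene LAMB3 (1.76, adjusted p = 0.00269) and TMEM158 (1.65, adjusted p = 0.000108) were higher. The collagenase MMP1 (-3.03, SE 0.24, adjusted p = 0.000529), the stromelysin MMP3 (-3.26, SE 0.34, adjusted p = 0.00272), TNFSF4 (-2.06, adjusted p = 0.000108), the metallothionein gene MT1G (-2.01, adjusted p = 0.0499) and CARD16 (-1.77, adjusted p = 0.000759) were lower. A further HAS3 probe gave -0.12. MT1G lost its call in 18 of 25 settings (adjusted p 0.0503 to 0.295), CYB5R2 in 9 of 25 (0.0503 to 0.15), MMP3 under quantile normalization (0.145) and F2RL2 under quantile normalization (0.088) and without replicate 1 of shRINT1 at 0 h (0.097). G2/M and mitosis (median -0.11, adjusted p = 0.724 with an estimated correlation) and oxidative phosphorylation (-0.18, 0.724) were called by camera, each at an adjusted p of 0.0318. These calls were lost in 7 and 8 of 25 settings, and the medians were -0.06 and -0.10 without replicate 2 of scramble at 0 h. At 24 h 160 features differed between the lines (82 higher, 78 lower, and 85 and 108 under normexp), at 48 h 1101 (706 higher, 395 lower) and at 96 h 5539 (2903 higher, 2636 lower, and 2680 and 2925 under quantile normalization). At 96 h 23 of 27 interferon-stimulated genes were lower in shRINT1 cells (median -1.71, camera adjusted p = 4.03e-18, and adjusted p = 0.00358 with an estimated correlation) and 23 of 34 G1/S genes were higher (median 0.87, camera adjusted p = 6.96e-12, and adjusted p = 0.032 with an estimated correlation). After GC correction the split at 48 h was 418 higher and 357 lower, and under normexp that before doxycycline was 41 higher and 43 lower. The count before doxycycline was 334 and 29 without replicates 1 and 2 of scramble at 0 h, 22 and 136 without replicates 1 and 2 of shRINT1 at 0 h, and 36 to 47 without an array of scramble at 24 or 48 h or of shRINT1 at 24 h. That at 24 h was 106 and 56 without replicates 1 and 2 of scramble at 24 h and 79 and 289 without those of shRINT1, and that at 48 h was 281 and 149 without replicates 1 and 2 of scramble at 48 h, 306 without replicate 1 of shRINT1 at 48 h and 727 without either scramble array of 24 h.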

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

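The tests on background, GC content and slide row for the wide response, and those on doxycycline itself and on noise of the 0 h arrays for the genes lower in one line, were chosen only after the result was seen. The tests of falls against rises were set before theirs.

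The lines differed in how they changed over time, by a test of the difference itself. The RINT1 hairpin response had 3 called features at 24 h, 3 at 48 h, where RINT1 was already at 25.1% of the scramble level, and 2829 at 96 h, and 2887 differed between 96 h and 24 h. With a common floor on all arrays 3333 features were called at 96 h, with the GC trend of the probes removed 2460, and between 96 h and 48 h, which share a slide row in both lines, 1973 (909 against 1465 from 0 h with no filter, and 1076 against 2442 without replicate 2 of scramble at 48 h). The floor puts dim features at 1 value and raised the counts of most comparisons, from 34 to 243 in scramble cells at 24 h. Its count therefore cannot decide on uneven background. With only features above background on all arrays 2824 were called, so the pattern is not one of dim features alone. Of the 2829 features, 2153 were still tested there and 2149 kept their call and direction. Mostly the same values entered both fits, so this overlap adds no support. The other values argue against probe GC content and slide row as the whole of the pattern. A delayed response to the loss of RINT1 stays open, as does an effect of the hairpin on other transcripts, since the lines carried 1 hairpin each. The response of RINT1 itself was not called at 24 or 48 h, so the few calls there do not show that few genes changed.

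Of 27 interferon-stimulated genes 12 rose in scramble cells by 96 h and 0 fell, while 20 fell and 1 rose in shRINT1 cells, with a median response of -1.83, and G1/S and DNA replication genes had a median response of 0.79. Both differences were tested with camera and passed with an estimated correlation as well.

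HSD17B10 (response 2.06 at 48 h) and NF2 (1.63 at 48 h) fell in scramble cells from 24 h on, with a difference between the lines, and SNU13 (-1.63 at 24 h) and KIF5B (-1.59 at 24 h) in shRINT1 cells. The 6 genes called lower in scramble cells at 48 h, at a median of -1.52, had a median of 0.087 in shRINT1 cells. The 16 called lower in shRINT1 cells, at -1.43, had a median of -0.069 in scramble cells. RINT1, the intended target, is among these 16. Both medians in the other line argue against doxycycline itself. Between lines at 48 h, where no array of 0 h enters, the same genes differed by 1.25 and -1.15. The arrays of 48 h had also served to select these genes, which favours such a difference. The values therefore argue only against noise of the 0 h arrays as the whole of the pattern. Over 12599 genes, 15 were lower by at least 0.5 at all 3 times in scramble cells alone against 101 higher. In shRINT1 cells alone 29 were lower against 58 higher. This meets neither the excess of falls set for unintended targets of a hairpin nor the even numbers set for drift of the lines. The 3 changes of a line share its 2 arrays of 0 h. Error in these arrays can enter all 3, so the split cannot decide between the 2 explanations. Unintended targets of a hairpin and drift of the lines both stay open, and the hairpin sequences are not given in the sources used here. The further NF2 probe changed by only -0.15 at 48 h and -0.20 at 96 h in scramble cells, against -1.52 and -1.79 for the called probe.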

How the results depend on the processing

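Limits are 2 arrays per group, the dimmer contrast of the 48 and 96 h arrays and 1 slide per line. A random block for slide was not run because it could not be estimated. RINT1 kept its call at 96 h in every setting, from -1.62 to -1.05 without single arrays. Of the 2829 features of the hairpin response at 96 h, 2043 were called in the same direction under normexp, 2472 under quantile normalization, 1462 with no filter, 2149 of the 2153 still tested with only features above background on all arrays, 2333 with the mean of probes, 2723 with trend and robust and 2818 in the value table. Of 412 values that were counts or the RINT1 level at 96 h, 296 were kept and 116 moved. Kept means within 1.5 times for a count, and the same direction and call for the 26 RINT1 values, all of which were kept. Of 1962 values of named genes 1773 kept direction and call, 186 lost the call and 3 gained it. Of 900 values of called lists 794 were kept, 105 lost the call and 1 reversed. The cause was not tested for results that changed. No filter adds features to the adjustment and the strict filter removes them, but this does not account for the rise of counts in scramble cells. With no filter 5554 features were higher there at 48 h and 8157 at 96 h. The lowest signal on scramble arrays was 2.08 to 2.29 at 0 and 24 h and 8.47 to 10.9 at 48 and 96 h. The raised background of the later arrays can enter those counts, but its share in them was not tested.

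Under normexp 55 features were called in scramble cells at 24 h, 1830 at 96 h (1390 higher, 440 lower) and 6 in the hairpin response at 48 h. The hairpin response then had 1 list at 24 h. Scramble cells at 96 h had 4 lists higher and 0 lower without normexp, and 7 lists with it, 1 higher and 6 lower. There the ER chaperone list had a median of 0.045 with a downward direction (adjusted p = 0.959), the reverse of its call. Quantile normalization gave 24 in scramble cells at 48 h and 5 in the hairpin response at 48 h, and a split of 1 higher and 1 lower at 24 h. With no filter the hairpin response had 0, 1 and 1465 calls at 24, 48 and 96 h and 1518 between 96 and 24 h. Scramble cells then had 14, 5773 and 8751, and the lines differed in 26, 49 and 250 at 0, 24 and 48 h. The median of all features was then 0.111 and 0.238 in scramble cells at 48 and 96 h, against -0.044 and 0.001 with the filter. With only features above background on all arrays the counts were 320 between lines at 24 h, 123 in scramble cells at 24 h and 20 in the hairpin response at 48 h. With trend and robust these 3 were 278, 89 and 18. The mean of probes gave 3 in scramble cells at 48 h and 0 in the hairpin response at 24 h.

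The replicate numbers did not pair the samples: of 28 pairs of groups 9 correlated over 0.1, from -0.209 to 0.277, across features above background on all arrays. With the replicate number as a block 39 features differed before doxycycline, 5 in scramble cells at 48 h, 0 in the hairpin response at 24 h and 2612 at 96 h. An estimated correlation called 1 list in the hairpin response at 48 h, 2 at 96 h and 1 in scramble cells at 96 h, and fry called 1 at 48 h and 11 at 96 h.

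A common floor and GC correction were chosen after seeing the data. With the floor 138, 378 and 1677 features differed between lines at 0, 24 and 48 h. Scramble cells had 243, 45 and 630, and the hairpin response had 11 at 24 h, 36 at 48 h and 3333 at 96 h, with 1 list at 24 h. Of the 2829 features 2652 were called in the same direction with the floor and 2375 after GC correction.

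Leaving out 1 array, with the lone array of its group assumed to vary like the others, gave 0 to 167 features in the hairpin response at 24 h, 1 to 208 at 48 h, 1881 to 2986 at 96 h and 1882 to 3028 between 96 and 24 h. Scramble cells had 14 to 266, 4 to 221 and 76 to 429, and the lines differed in 22 to 334, 56 to 289 and 149 to 1372 at 0, 24 and 48 h. The hairpin response had 0 to 5 lists at 24 h (5 without replicate 2 of scramble at 0 h), 1 to 7 at 48 h (1 without replicate 2 of shRINT1 at 0 or 48 h, 3 without replicate 1 of scramble at 0 h or replicate 2 at 48 h) and 6 to 8 at 96 h. Scramble cells at 96 h had 2 to 7 (2 and 7 without replicates 1 and 2 of 96 h).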

Other observations

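The gene families below, the correlation between lines and the test of doxycycline or days acting alike were chosen after the result was seen. The other tests were set before theirs.

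Beside the 24 lists, genes were grouped into 26 families by the start of their symbol, and some of these genes are also in a list. Of these families 9 were called by camera in the hairpin response at 96 h, and 0 were called with an estimated correlation. Of 61 measured canonical histone genes 24 were higher and 0 lower, with a median of 0.81 (camera adjusted p = 4.91e-13, adjusted p = 0.263 with an estimated correlation). H2AC13 (1.44, SE 0.23, adjusted p = 0.00298), H2AC16 (1.37, adjusted p = 0.00305) and H2BC6 (1.30, adjusted p = 0.00294) were examples. Of 6 HLA class I genes, which present peptides to T cells, 5 were lower, with a median of -1.20 (camera adjusted p = 1.36e-05, adjusted p = 0.122 with an estimated correlation). HLA-C was at -1.65 (SE 0.14, adjusted p = 0.000121), HLA-G at -1.32 (adjusted p = 0.000644) and HLA-F at -1.11 (adjusted p = 0.011). These genes are near copies, and a probe can bind more than 1 of them.

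Of 26 collagen genes 6 were lower and 0 higher (median -0.13, camera adjusted p = 0.028, adjusted p = 0.487 with an estimated correlation). COL6A2 was at -2.88 (SE 0.43, adjusted p = 0.00192, well above background on 1 of 2 shRINT1 arrays of 96 h), COL5A1 at least 2.63-fold lower (adjusted p = 0.00159, on neither of them) and COL6A1 at -1.55 (adjusted p = 0.00718). Of 11 laminin symbols, 1 of them a pseudogene, 5 were lower (median -0.80, camera adjusted p = 0.00404, adjusted p = 0.34 with an estimated correlation), among them LAMB1 (-1.26, adjusted p = 0.0036), LAMC3 (-1.22, adjusted p = 0.0155) and LAMB3 (-1.02, adjusted p = 0.0256), each well above background on 1 of 2 shRINT1 arrays of 96 h, and LAMA2 (-0.73, adjusted p = 0.0272), and the fifth was the pseudogene. Of 19 V-ATPase symbols, named for the proton pump of lysosomes and Golgi and with 1 antisense transcript among them, 4 were higher (median 0.35, camera adjusted p = 0.00247, adjusted p = 0.34 with an estimated correlation). They were ATP6V0C (1.29, adjusted p = 0.000913), ATP6V0B (0.95, adjusted p = 0.0142), ATP6V0D1 (0.93) and the antisense transcript. The other 4 families called were mitochondrial ribosomal proteins (6 of 76 higher, median 0.36, camera adjusted p = 0.000819), genes with NOP, UTP, EXOSC, DDX, NOL or WDR symbols (20 of 109 higher and 5 lower, median 0.33, adjusted p = 0.00342), translation initiation factors (11 of 51 higher and 2 lower, median 0.26, adjusted p = 0.00404) and nucleoporins (1 of 22 higher, median 0.36, adjusted p = 0.0124). With an estimated correlation their adjusted p-values were 0.572, 0.258, 0.371 and 0.461. The medians of the 5 families named first kept their sign under normexp, quantile normalization, the value table and GC correction.

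The change in shRINT1 cells at 96 h resembled that in scramble cells at 24 h in part, and so did the change in shRINT1 cells at 24 h. Across genes, which are not independent replicates, the change in scramble cells at 24 h correlated with that in shRINT1 cells at r = 0.269 at 24 h (Spearman 0.359), 0.052 at 48 h and 0.25 at 96 h (Spearman 0.287), and the change in shRINT1 cells at 96 h with that in scramble cells at 0.002 at 48 h and 0.086 at 96 h, where the sides share no array. Of the 34 features called in scramble cells at 24 h, 32 had the same sign in shRINT1 cells at 24 h, 20 at 48 h and 30 (88.2%) at 96 h. The correlation with 96 h was 0.242 without the 125 genes of the interferon, G1/S, G2/M and DNA damage lists and 0.244 after GC correction. Leaving out 125 of 20557 features could hardly lower it, and other genes that move with those lists can remain. The first value therefore shows only that the correlation does not rest on the listed genes. The second argues against GC content. The arrays of 24 and 96 h shared slide columns that those of 0 and 48 h did not. An effect of column can therefore enter these correlations and signs. The change in scramble cells at 96 h, from the same columns, correlated with that in shRINT1 cells at only -0.072 at 24 h and 0.086 at 96 h. Slide column was not tested further. The interferon-stimulated genes had a median of 0.79 in scramble cells at 96 h, which argues against doxycycline or days in culture acting alike in both lines. A growth state at 96 h shared with the cells at 24 h stays a hypothesis, and no cell counts were analysed here.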
